A study of Homo sapiens with 6 samples.

How the data were processed

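Total RNA from T24 bladder cancer cells was extracted with Trizol 48 h after transfection with negative control or G9a siRNA, the cells having been seeded 24 h before transfection, per the labels' protocols. Biotinylated single-stranded cDNA was made from 500 ng of total RNA with an Affymetrix whole-transcript kit, per the labels' protocols. The deposited values are log2 expression per probe set, which the authors made with RMA, per the submitters' processing notes. RMA corrects the background, normalizes the arrays to a common distribution and summarises the probes of a probe set. The software, its version and the annotation build are not given in the sources used here. That the values are log2 was read from their range and from array medians of 6.69 to 6.70 over all rows. Because the arrays were forced to nearly the same distribution, a change in the total amount of messenger RNA per cell cannot be seen in these values, and each change is relative to the other genes.

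The table holds 24351 rows. The 2903 control rows (antigenomic background, spike-in, ERCC, and positive and negative exon and intron probe sets) were left out, and 21448 transcript probe sets were tested. No column of another sample was present. The platform annotation used here gives 1 gene symbol for 17709 of these, several for none, and no name here for 3739. All 17709 Entrez identifiers were found in the RefSeq gene table of GRCh38.p14, and no symbol needed an update. They stand for 17687 genes, of which 20 have more than 1 probe set. Gene-level tests used the probe set with the highest mean over the 6 arrays. No coordinates are given because the build behind the probe sets is not stated in the sources used here.

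Samples were grouped by their titles into siNC and siG9a, with 3 arrays each. No array pair shared more than 4 identical values, and the SD of the difference between 2 replicates of a group was 0.232 to 0.245, so no array was a copy of another. The labels give no batch or scan date. The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided moderated test, no covariate; 4 residual and 4.24 prior degrees of freedom) over all 21448 probe sets with Benjamini-Hochberg adjustment, and an adjusted p below 0.05 was called a change. Every adjusted p of a gene comes from this fit. The study's own selection, stated without a test, was applied to the same fit (unadjusted p of at most 0.001 and a fold change of at least 1.5). Standard errors are those of the moderated fit. A probe set not above the 95th percentile of the negative controls on any array of a group has only a bound there. Its fold is given as at least the difference, taken out of log2, between the brighter group's mean and the dimmer group's mean of, per array, the higher of that percentile and its own value. No fold is given where this holds in both groups. This check was added after seeing the data. Of the 1778 changed probe sets, 24 were not above it on any array of siNC alone, 41 of siG9a alone and 55 of both groups, and a further 35 were above it on only some arrays of a group. Array intensities are not counts, so no counting interval applies.

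The design, the alternatives and 33 gene lists of 846 genes were fixed before the data were examined. Of these genes 738 were measured under a name, 1 of them through a synonym. The list of mitochondrially encoded genes had no measured member under a name and was not analysed here, and lists needed at least 5 measured members. Lists were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over 32 lists. Camera with an estimated correlation and fry were alternatives. The count adjusted over the list alone applies Benjamini-Hochberg to the members only. The lists overlap in part, and inflammatory or mesenchymal genes are expressed by T24 cells themselves.

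The genes named in the text follow a rule fixed beforehand: EHMT2 and EHMT1; the 12 largest rises and the 12 largest falls among named genes with an adjusted p below 0.05 and groups that do not overlap; and for each list up to 2 passing members per direction with the largest change, or the 2 smallest p-values where none passed. Unnamed loci, small RNA precursors, pseudogenes, olfactory receptors, XIST and Y-linked genes were excepted. Further list members in the text, and the gene families in the closing section, were chosen after their values were seen.

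The alternatives were leaving out each array, the replicate number as a block, median centring, repeated quantile normalization, a brightness trend and robust prior, array weights, filters at the 25th percentile and at the median of brightness, no variance shrinkage, an adjusted p below 0.01, limma's treat against a fold of 1.5, 1 probe set per gene, and averaging the probe sets of a gene. EHMT2 has 1 probe set, so averaging its probe sets was not run. Cyclic loess normalization, scaling to the 4 poly-A spike-in probe sets and lists without EHMT2 were added after seeing the data. The fit was tested on simulated data with the real means and spreads of all 21448 probe sets and 200 changed ones among the brighter ones. It recovered 74% of the changes of 1.5-fold and 99% of those of 2-fold, and 7.94% of all calls were unchanged probe sets. A list shifted by 0.3 was called and no other list was. Camera assumes a low correlation between genes, which these simulated data had by construction.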

Results

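Gene expression was profiled in T24 cells, an established human bladder cancer line, after transfection with a negative control siRNA (siNC) or an siRNA against G9a (siG9a). G9a is the histone H3 lysine methyltransferase encoded by EHMT2, which acts mainly on lysine 9 together with its partner GLP, encoded by EHMT1. Each group held 3 arrays, 6 in all, and RNA was taken 48 h after transfection. The measurements are log2 expression values for 21448 transcript probe sets. Array medians lay between 6.54 and 6.57, and the share of probe sets brighter than the 95th percentile of the negative control probe sets on the same array was 76.1% to 77.2% in siNC and 72.8% to 75.1% in siG9a, ranges that do not overlap. That percentile was 4.96 to 5.03 in siNC and 5.04 to 5.23 in siG9a, and a probe set brighter than it is called above the negative controls below. Replicates of a group correlated at r = 0.9921 to 0.9929 across probe sets, and arrays of different groups at 0.9850 to 0.9871. The labels do not say whether the replicates came from separate transfections, so p-values measure the spread between these 6 arrays, which may be technical. The small number of arrays limits the precision of every value.

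The siRNA target was lower in every siG9a array. EHMT2 stood at 7.41 ± 0.083 (SD, n = 3) in siNC and at 6.43 ± 0.066 (SD, n = 3) in siG9a, a log2 change of -0.98 with a 95% confidence interval from -1.18 to -0.77. The siG9a level was therefore 50.8% of the control level, with an interval from 44.2% to 58.5% (limma, adjusted p = 0.000998). This interval covers the spread between arrays and not the choice of normalization. Scaled to the poly-A spike-ins, the log2 change of EHMT2 was -1.27, outside it. Tested against a fold change of 1.5 in place of no change, the fall did not pass after adjustment over all 21448 probe sets (limma treat, adjusted p = 0.243). The 95% interval of this gene alone, which is not adjusted, lay wholly beyond a 1.5-fold fall, a size of 0.585 on the log2 scale. The 3 siNC arrays read 7.49, 7.41 and 7.32, and the 3 siG9a arrays 6.36, 6.44 and 6.49. EHMT1 rose, from 8.14 ± 0.12 to 8.52 ± 0.026 (log2 change 0.38, SE 0.091, adjusted p = 0.0398), although it passed in 7 of 19 alternative fits, and in none of the 6 that left out an array. Of the 23 measured genes of the H3K9 methylation machinery, 2 rose, 2 fell and 19 did not pass. SUV39H2, another H3K9 methyltransferase, rose by 0.72 on the log2 scale, and the H3K9 demethylase gene KDM4C fell by 0.48. Adjusted over the list alone, 4 members rose and 2 fell, EHMT2 itself being among the falls, and the list with all its members did not pass (camera, adjusted p = 0.144). Without EHMT2, an alternative chosen after seeing the data, 17 of 22 members had positive values with a median of 0.15, and the list passed as higher (camera, adjusted p = 0.0464), but not with fry (adjusted p = 0.0667; adjusted p = 0.486 with camera and an estimated correlation).

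The comparison the study was designed for, siG9a against siNC, gave changes in both directions of similar number. The labels name no further G9a siRNA and no rescue. Effects of the siRNA on other transcripts therefore cannot be told apart from effects of losing G9a. At an adjusted p below 0.05, 1778 of 21448 probe sets differed, of which 922 were higher and 856 lower in siG9a. They include 1587 named genes, of which 819 were higher and 768 lower. The selection stated by the study, an unadjusted p of at most 0.001 with a fold change of at least 1.5, kept 577 probe sets, 259 higher and 318 lower, and all 577 also passed the adjusted threshold. Changes of at least 1 on the log2 scale were seen for 43 probe sets that rose and 70 that fell. The groups did not overlap for 30.6% of all probe sets, against 10% expected by chance for 3 arrays against 3. Leaving out any 1 of the 6 arrays lowered the count at adjusted p below 0.05 by over 1.5 times, to between 785 (without siG9a replicate 3) and 996 (without siG9a replicate 2). The 4 poly-A spike-in controls had uneven changes of 0.10 to 0.54. Scaling the arrays to their mean shifted the median of all probe sets from -0.01 to -0.31 and gave a count of 9488, with 254 higher and 9234 lower, so all changes below are relative to the bulk of the genes on the array.

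**Figure D1:**
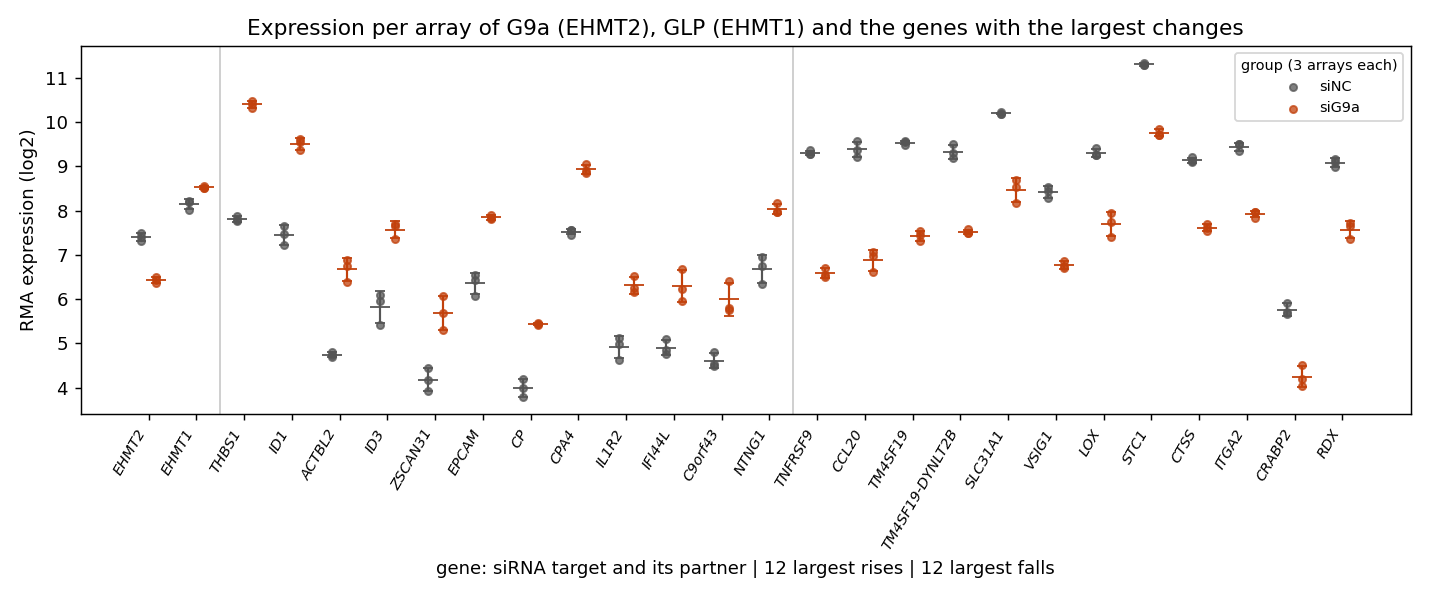
RMA expression (log2, vertical axis) of EHMT2, EHMT1 and the 12 genes with the largest rises and the 12 with the largest falls; each point is 1 array, the horizontal marks are group means and the bars are SDs over 3 arrays. The 3 siG9a points of EHMT2 lie between 6.36 and 6.49, all below the siNC points, and for each of the 26 genes the groups do not overlap.

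THBS1, which encodes the secreted matrix protein thrombospondin-1, rose most among named genes, from 7.81 ± 0.061 to 10.4 ± 0.081 (log2 change 2.58, SE 0.087, adjusted p = 1.21e-05). ID1 and ID3, inhibitors of basic helix-loop-helix transcription factors, rose by 2.06 (SE 0.13) and 1.75 (SE 0.18) on the log2 scale. The actin-like gene ACTBL2, not above the negative controls on any siNC array, was at least 3.22-fold higher in siG9a (adjusted p = 0.000363), and the cell adhesion gene EPCAM rose by 1.49 (SE 0.13). The carboxypeptidase CPA4 rose by 1.40 and the axon guidance gene NTNG1 by 1.35. The decoy receptor IL1R2 (1.40) and the interferon-inducible IFI44L (1.39) were above the negative controls on 2 and 1 of the 3 siNC arrays, so the sizes of their rises are uncertain. The remaining genes among the 12 largest fitted rises were not above the negative controls on any siNC array and have only lower bounds: C9orf43 was at least 2.01-fold (adjusted p = 0.00412), the zinc finger gene ZSCAN31 at least 1.62-fold (adjusted p = 0.00466) and the copper-carrying ferroxidase CP at least 1.37-fold (adjusted p = 0.000615) higher in siG9a.

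TNFRSF9, a receptor of the tumour necrosis factor family also called 4-1BB, fell most, from 9.30 ± 0.050 to 6.59 ± 0.10 (log2 change -2.71, SE 0.090, adjusted p = 1.21e-05). The chemokine CCL20 followed with a log2 change of -2.50 (SE 0.14). TM4SF19 changed by -2.11, and the read-through locus TM4SF19-DYNLT2B, whose signal cannot be told apart from that of TM4SF19 where they overlap, by -1.81. The copper importer SLC31A1 changed by -1.72 (SE 0.13), the junction protein gene VSIG1 by -1.64, the collagen cross-linking enzyme LOX by -1.61 and the secreted glycoprotein hormone STC1 by -1.54. The lysosomal protease CTSS (-1.53), the collagen receptor subunit ITGA2 (-1.52) and the membrane-cytoskeleton linker RDX (-1.51) followed. The retinoic acid binding protein CRABP2, also among the 12 largest fitted falls, was not above the negative controls on any siG9a array and was at least 1.55-fold lower there (adjusted p = 0.000998).

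Across 32 gene lists fixed before the data were examined and tested with camera, 10 shifted relative to all other genes, 6 higher and 4 lower. None of the 10 passed when the correlation between genes was estimated from these 6 arrays, where the lowest adjusted p was 0.161. For the TGF-beta and YAP targets (-0.00275) and the lysosomal genes (0.00582) the estimated correlation lay below the preset of 0.01. A stronger correlation between genes is therefore not why these lists did not pass. The unadjusted camera p of the TGF-beta and YAP targets still went from 8.03e-06 to 0.00809. With an estimated correlation, camera takes its p-values from the 4 residual degrees of freedom, which leaves it little power. A list that did not pass there is therefore not shown to owe its call to correlated genes. The rotation test fry, which asks whether the genes of a list move on balance in 1 direction without comparing them with other genes, called 15 lists. These were 9 of the 10 and 6 that camera did not call: autophagy, the BCL2 family and caspases, endoplasmic reticulum chaperones, protocadherins and leukocyte markers, all lower, and NRF2 targets, higher.

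**Figure D2:**
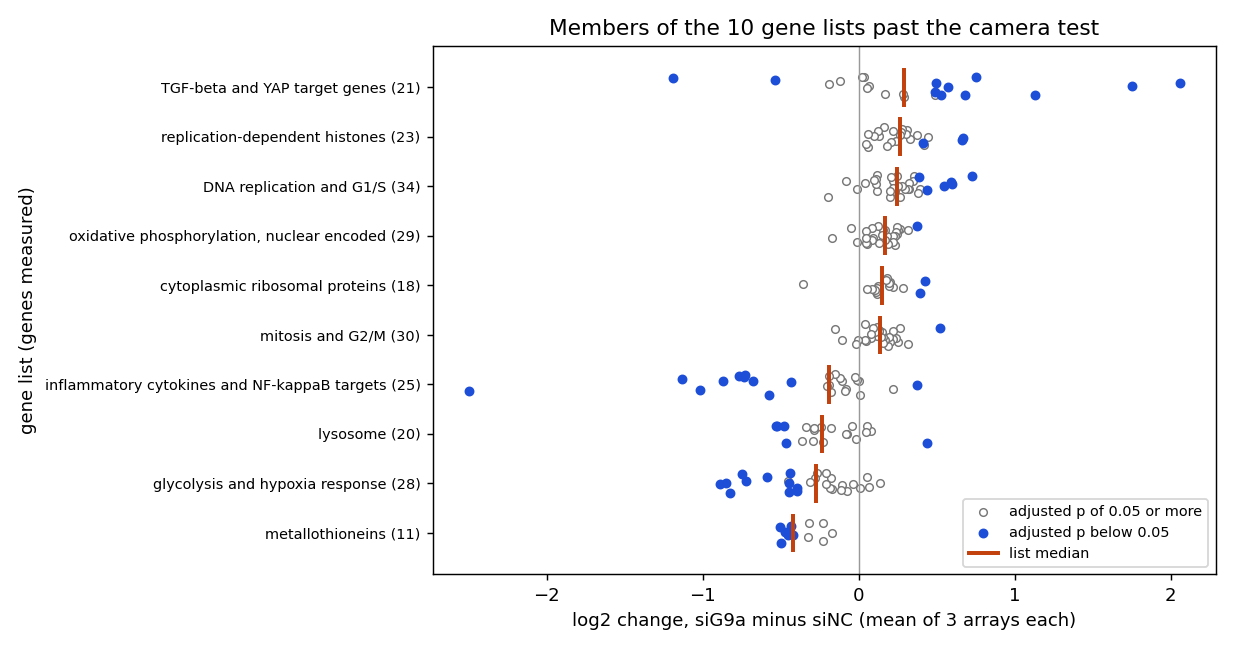
Log2 change between siG9a and siNC (horizontal axis) of each measured member of the 10 gene lists past the camera test; filled points are members with an adjusted p below 0.05, open points the others, and vertical bars the list medians, which run from -0.42 for the metallothioneins to 0.29 for the TGF-beta and YAP targets. Scaling to the poly-A spike-ins lowered every value by 0.29, which puts the medians of all 6 upper lists below 0.

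Inflammatory cytokines and NF-kappaB targets were lower in siG9a cells. Of 25 measured genes, 10 fell, 1 rose and 14 did not pass, and the counts adjusted over the list alone were the same (10 and 1). After CCL20, the largest falls were those of TNFAIP3, which encodes the NF-kappaB inhibitor A20 (-1.13, SE 0.083), and of CXCL8, the neutrophil chemoattractant interleukin-8 (-1.02). IL1A (-0.87), IL6 (-0.77), CSF3 (-0.74), CXCL5 (-0.73), ICAM1 (-0.68) and IL1B (-0.57) also fell, whereas CXCL1, whose sequence resembles that of its neighbours CXCL2 and CXCL3, rose by 0.37. The rise of CXCL1 passed in 9 of 19 alternative fits. The median of the list was -0.19 (camera, adjusted p = 3.77e-06; adjusted p = 0.161 with an estimated correlation). The leukocyte markers, measured as a check for other cells, had a median of -0.14, 1 of 19, the macrophage gene CD68 (-0.96), fell, and fry called that list lower too.

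Interferon-stimulated genes went both ways. Of 36 measured, 4 rose and 8 fell, and 6 rose and 10 fell when adjusted over the list alone. IFI44L and IFI6 (1.14, SE 0.11) rose together with IFIH1 (0.46) and IFI27 (0.43). Among those that fell were IFIT2 (-1.12, SE 0.088), SAMD9 (-1.04), the RNA sensor RIGI (-0.85), IFIT1 (-0.79) and IFIT3 (-0.72), and the IFIT genes are similar enough in sequence for single values to be uncertain. The list as a whole did not shift (camera, adjusted p = 0.445). Of 16 genes for antigen presentation by MHC class I, 1 rose, the immunoproteasome subunit PSMB9 (0.62), and 2 fell, TAPBP (-0.70) and ERAP1 (-0.38), with 3 and 2 adjusted over the list alone (camera, adjusted p = 0.771).

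Genes of the TGF-beta and YAP target list were higher in siG9a cells. Of 21 measured, 9 rose and 2 fell, and 11 rose and 2 fell adjusted over the list alone. Besides ID1 and ID3, these were the actin-binding TPM1 (1.13), AJUBA (0.75), LTBP2 (0.68), the receptor tyrosine kinase AXL (0.57), MYL9 (0.53), PMEPA1 (0.50) and CCN1 (0.49). ANKRD1, a widely used YAP target, fell by 1.19 on the log2 scale and INHBA by 0.54. The median was 0.29 (camera, adjusted p = 4.28e-05; adjusted p = 0.161 with an estimated correlation).

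Genes of glycolysis and the hypoxia response were lower. Of 28 measured, 11 fell and none rose, and 12 fell and none rose adjusted over the list alone. The carbonic anhydrase CA12 (-0.89, SE 0.10), the glycolytic enzymes ALDOC (-0.85), ENO2 (-0.82), PGK1 (-0.45), GPI (-0.45), TPI1 (-0.40) and PGAM1 (-0.39), NDRG1 (-0.75), BNIP3 (-0.72) and the collagen prolyl hydroxylases P4HA1 (-0.59) and P4HA2 (-0.44) fell. The median was -0.27 (camera, adjusted p = 5.29e-08; adjusted p = 0.161 with an estimated correlation). The metal-binding metallothionein list lay lower too: all 11 measured members had negative values, 6 fell, among them MT1G (-0.51) and MT1F (-0.50), and 9 fell adjusted over the list alone. Its median was -0.42 (camera, adjusted p = 3.53e-06; adjusted p = 0.459 with an estimated correlation), and because the MT1 genes are near-identical copies their single values are uncertain.

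Lysosomal genes were lower, and autophagy genes were called lower by fry but not by camera. Of 20 lysosomal genes, 4 fell and 1 rose, or 10 and 1 adjusted over the list alone, with GLA (-0.53), CTSA (-0.53), CTSL (-0.48) and NPC1 (-0.47) lower and the proton pump subunit ATP6V1A (0.44) higher. Their median was -0.24 (camera, adjusted p = 0.00143; adjusted p = 0.161 with an estimated correlation). Of 38 autophagy genes, 5 fell and none rose, namely GABARAPL1 (-0.79), BNIP3, the cargo receptor SQSTM1 (-0.44), WIPI1 (-0.42) and ATG5 (-0.35), and 8 fell and 2 rose adjusted over the list alone (camera, adjusted p = 0.0506; fry, adjusted p = 0.0229). In the AMPK and mTOR list, 2 of 29 rose, the AMPK subunits PRKAA2 (0.59) and PRKAB2 (0.39), and 4 fell, among them EIF4EBP1 (-0.56) and RRAGC (-0.42), with 2 and 5 adjusted over the list alone (camera, adjusted p = 0.399). PRKAA2 and PRKAB2 each passed in 8 of 19 alternative fits, EIF4EBP1 in 12 and RRAGC in 10.

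DNA replication genes and replication-dependent histones lay higher in siG9a cells. Of 34 replication and G1/S genes, 6 rose and none fell, and 16 rose and none fell adjusted over the list alone. They were the cyclin CCNE2 (0.73, SE 0.11), GINS2 (0.60), the licensing factor CDC6 (0.59), GINS1 (0.54), MCM3 (0.44) and MCM7 (0.38), and the list median was 0.25 (camera, adjusted p = 5.29e-08; adjusted p = 0.161 with an estimated correlation). As normalized by the authors, all 23 histone genes had positive values with a median of 0.26, and 3 rose, H3C10 (0.67), H2BC14 (0.66) and H2AC11 (0.41), or 10 adjusted over the list alone (camera, adjusted p = 1.19e-06; adjusted p = 0.459 with an estimated correlation). Histone genes are near-identical copies, so single values are uncertain.

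Smaller shifts in the same direction were measured for 3 further lists. Of 30 mitotic genes, 26 had positive values, and CDC20 (0.52) alone rose, also when adjusted over the list alone; the median was 0.13 (camera, adjusted p = 0.00173; adjusted p = 0.549 with an estimated correlation). This list did not pass with fry (adjusted p = 0.0806) or after scaling to the poly-A spike-ins (adjusted p = 0.0601). Of 29 nuclear-encoded oxidative phosphorylation genes, COX4I1 (0.38) rose, also when adjusted over the list alone, and 26 had positive values with a median of 0.17 (camera, adjusted p = 0.000232; adjusted p = 0.175 with an estimated correlation). Of 18 measured cytoplasmic ribosomal protein genes, RPS14 (0.42) and RPL27 (0.40) rose, with 3 up and 1 down adjusted over the list alone and a median of 0.15 (camera, adjusted p = 0.00134; adjusted p = 0.459 with an estimated correlation). The full ribosomal list holds 36 genes, of which these 18 were measured under a name. It did not pass after scaling to the poly-A spike-ins (camera, adjusted p = 0.0872). The probe sets of these 3 lists were bright, with mean levels of 9.35, 9.44 and 11.3, and the median change of all probe sets rose from -0.05 in the fourth to 0.04 in the tenth decile of brightness.

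Apoptosis, p53 target and stress response lists did not pass camera, while fry called the BCL2 family and caspase list and the endoplasmic reticulum chaperones lower. In the BCL2 family and caspase list, 3 of 28 rose and 4 fell, or 4 and 6 adjusted over the list alone, and 21 of 28 had negative values. The pro-apoptotic BCL2L11, which encodes BIM, rose by 0.60 (SE 0.12) and the caspase CASP2 by 0.41, while the anti-apoptotic BCL2A1 (-1.14, above the negative controls on 1 of 3 siG9a arrays) and the apoptosome component APAF1 (-1.09) fell (camera, adjusted p = 0.105; fry, adjusted p = 0.017). Of 22 p53 targets, 4 fell and none rose, or 6 and 1 adjusted over the list alone: the cell cycle inhibitor CDKN1A (-0.89, SE 0.10), TIGAR (-0.46), GDF15 (-0.44) and the death receptor TNFRSF10B (-0.42) (camera, adjusted p = 0.144). Among 30 ATF4 targets and serine synthesis genes, 5 rose and 4 fell, or 7 and 7 adjusted over the list alone, with the amino acid transporter subunits SLC7A5 (1.09, SE 0.096) and SLC3A2 (0.66) higher and VLDLR (-0.51) and CTH (at least 1.34-fold, adjusted p = 0.0101, not above the negative controls in siG9a) lower (camera, adjusted p = 0.833). Of 20 endoplasmic reticulum chaperone genes, 4 fell and none rose, or 4 and 2 adjusted over the list alone, led by DNAJB11 (-0.94) and DNAJB9 (-0.68) (camera, adjusted p = 0.341; fry, adjusted p = 0.0396).

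Cell identity lists did not shift as a whole. Among 24 epithelial junction genes, 3 rose and 3 fell in both counts, with EPCAM and TJP1 (0.37) higher and DSC2 (-0.59), CLDN4 (-0.59) and OCLN (-0.52) lower (camera, adjusted p = 0.723). Among 27 mesenchymal genes, 5 rose and 6 fell, or 5 and 7 adjusted over the list alone, with THBS1, TGFBI (1.21, SE 0.086) and CDH2 (0.50) higher and LOX, ITGA5 (-0.72), MMP14 (-0.72) and COL6A1 (-0.69) lower (camera, adjusted p = 0.771). For this list the mean (0.02) and the median (-0.04) differ in sign. Of 20 urothelial luminal genes, the keratins KRT7 (0.78, SE 0.085) and KRT8 (0.37) rose and the fatty acid binding FABP4, not above the negative controls in siG9a, was at least 1.51-fold lower (adjusted p = 0.00566), with 3 up and 2 down adjusted over the list alone; here the median was 0.006 and the mean -0.03 (camera, adjusted p = 0.693). None of 19 basal and squamous genes passed in either count, and the smallest p-values were those of KRT1 (0.42, adjusted p = 0.0811, above the negative controls on 2 of 3 siNC arrays) and IVL (adjusted p = 0.149), the latter not above the negative controls on any array, with a list p of 0.445 after adjustment.

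Of 30 cancer-testis and germline genes, HORMAD1 (-0.57, above the negative controls on 1 of 3 siG9a arrays) fell and none rose, and none passed adjusted over the list alone (camera, adjusted p = 0.723). Of 27 neuronal genes repressed by REST, the adhesion molecule L1CAM rose by 1.25 (SE 0.091), and SNAP25 (-0.94) and CHGA (at least 1.12-fold, adjusted p = 0.0438, not above the negative controls in siG9a) fell, with the same counts over the list alone (camera, adjusted p = 0.492). The fall of CHGA passed in 5 of 18 alternative fits. Of 12 measured protocadherin genes, 2 passed as lower, PCDHB12 (-0.39) and PCDHB15 (adjusted p = 0.0144), which was not above the negative controls on any array, so no fold is given, or 3 adjusted over the list alone (camera, adjusted p = 0.141), and fry called the list lower (adjusted p = 0.0143).

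Of 19 measured NRF2 targets, 4 rose and none fell, ME1 (0.63), NQO1 (0.53), TKT (0.48) and SLC7A11 (0.46), with 5 up and 4 down adjusted over the list alone (camera, adjusted p = 0.492; fry, adjusted p = 0.0454, higher). Of 19 cholesterol synthesis genes, IDI1 (0.37) rose and STARD4 (-0.51) fell in both counts (camera, adjusted p = 0.749), and the list's median (-0.03) and mean (0.02) differ in sign. Of 25 immediate early and heat shock genes, the mitochondrial chaperone HSPD1 (0.48) rose and 3 fell, among them the phosphatases DUSP5 (-0.995, SE 0.084) and DUSP6 (-0.56), with 1 and 4 adjusted over the list alone (camera, adjusted p = 0.733). Lists of markers of other cell types did not pass camera. For leukocytes the adjusted p was 0.445, with 1 of 19 lower in both counts, but fry called the list lower (adjusted p = 0.0246). For endothelium the camera adjusted p was 0.187, with 3 of 15 lower in both counts, ESAM (-0.72), CLDN5 (-0.51) and ENG (-0.35). For fibroblasts and smooth muscle it was 0.811, with none of 14 past the threshold in either count and the smallest p-values at FAP (adjusted p = 0.0679), not above the negative controls on any array, and PDGFRA (-0.29, adjusted p = 0.228).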

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

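The tests of the poly-A controls and of the leukocyte markers were chosen only after the values they concern had been seen.

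Controls that the comparisons do not use differed between the groups: the 4 poly-A spike-in controls, bacterial RNAs mixed into the RNA before labelling, averaged 5.56 ± 0.036 (SD, n = 3) in siNC and 5.85 ± 0.071 (SD, n = 3) in siG9a, a difference of 0.294 on the log2 scale (1.23-fold, exact two-sided permutation p = 0.1, the smallest this design allows). The single spike-ins were uneven, with changes of 0.543 for thr, 0.308 for phe, 0.223 for dap and 0.10 for lys, and lys read 3.72 in siNC, below the negative controls' 95th percentile of 4.98, with 1 siG9a array (3.67) below the siNC arrays. A trend with brightness as the whole cause is argued against, since each of the 4 rose more than equally bright transcripts, by 0.325 on average (SE 0.10 over the 4). As a part of the cause, it would need equally bright transcripts to rise. Their median change was negative for phe (-0.0587), thr (-0.0496) and lys (-0.0378), which argues against it for these spike-ins. For dap it was 0.021, so a small part stays open there. The bound first set could not decide this. The average of these medians, -0.0313, lay above that bound of -0.04, taken from the SE over the 4 spike-ins. It lay below the bound of 0.055 from the SE between arrays, which was tried after that outcome was seen. Hybridization or scanning stays open. The 4 hybridization controls, added after labelling, differed by 0.0947. Their difference from the spike-ins had an exact permutation p of 0.0857, from exchanging control probe sets and not arrays. A lower share of messenger RNA in the total RNA of siG9a cells and a larger amount of added spike-in cannot be told apart, because both predict the measured 0.294 and the amounts added are not given in the sources used here.

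The 5 lists of replication, histone, mitotic, ribosomal protein and oxidative phosphorylation genes lay higher in siG9a arrays, and probe sets in the upper deciles of brightness did so as well. So did the 2197 positive exon controls, which no comparison uses. Their array means were 9.251 to 9.273 in siNC and 9.345 to 9.386 in siG9a, a difference of 0.105 between the groups. The cause of that difference was not tested. If a trend with brightness were the whole cause, random lists of equally bright genes would reach the same medians. The medians of 5 of the 5 lists lay above the 95th percentile of 10000 random lists matched on brightness. Camera had called these lists higher in the same arrays, and the random lists were not picked that way. Lists that camera did not call also lay far out, at percentiles of 97.62 (H3K9) and 0.61 (BCL2 family). The test therefore cannot decide for the mitotic (96.86), ribosomal protein (98.28) and oxidative phosphorylation genes (99.52). For the replication genes and the histones (both at 100), medians of 0.248 and 0.262 exceeded random 95th percentiles of 0.0928 and 0.112. This argues against brightness as the whole cause for these lists. Random lists ignore correlation between genes, and a biological effect of the siRNA on proliferation stays open as an untested hypothesis.

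The inflammatory and NF-kappaB list lay lower in siG9a arrays, with a mean change of -0.407. A trend with brightness is argued against, since the median of the list stood at the 0.05th percentile of 10000 random lists matched on brightness. Low levels go against a large share of RNA from leukocytes in the siNC cultures: in siNC 11 of 19 leukocyte markers lay below the negative controls' 95th percentile (4.98), among them the widely expressed PTPRC (4.11), LYZ (3.37), AIF1 (3.26) and FCER1G (4.52). A small share of leukocytes with very high cytokine levels stays open, since markers near background cannot exclude it. All 8 above that percentile, TYROBP (7.48) among them, were lower in siG9a, with a median change of -0.161 (SE 0.10). This was too close to the bound of -0.203, a set fraction of the inflammatory list's mean change of -0.407. That bound sets a median of markers against a mean of the list, so it cannot decide. The median of the inflammatory list was -0.188. The whole leukocyte list was lower in fry (adjusted p = 0.0246), with its median at the 1.67th percentile of matched lists. Of the 11 markers below that percentile in siNC, 7 were higher in siG9a. The labels name a cell line, for which no leukocytes are described.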

How the results depend on the processing

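Cyclic loess, scaling to the poly-A spike-ins and lists without EHMT2 were chosen after seeing the data, the other alternatives before the data were examined. EHMT2 was lower and past the threshold in its alternatives except treat against a fold of 1.5, a stricter test by construction (log2 change -0.9765, adjusted p = 0.243, range over its alternatives 2.17e-06 to 0.243), with log2 changes of -1.018 to -0.9352 when 1 array was left out (adjusted p 0.00573 to 0.00748). The count of 1778 changed probe sets (922 higher, 856 lower) became 3499 (1994 and 1505) with a trend and robust prior, 3121 (1762 and 1359) at or above the median brightness, 935 (456 and 479) without variance shrinkage, 518 (230 and 288) at an adjusted p below 0.01, 38 (13 and 25) against a fold of 1.5 with treat, and 9488 (254 and 9234) scaled to the spike-ins; at or above the 25th percentile of brightness 1395 were higher. The stricter threshold and treat call fewer by construction, and for the others the cause was not tested. The study's selection of 577 became 268 (98 and 170) without shrinkage and 1732 (61 and 1671) scaled to the spike-ins. Without 1 array, which leaves fewer samples, the changed probe sets numbered 785 (without siG9a replicate 3) to 996 (without siG9a replicate 2), with 373 to 480 higher and 395 to 527 lower, and the selection 487 to 540, with 192 to 260 higher and 259 to 305 lower. With the replicate number as a block, 1063 changed (533 and 530). The numbers were not taken to pair the samples, since same-numbered arrays had correlations of 0.078, 0.12 and 0.0066 between their deviations, not all above 0.1, and in 2 of 3 pairs each siG9a array matched its own number best. As a hint the other way, the second principal component (15.6%) put the siNC and siG9a arrays of replicate 2 together (-14.1 and -16.1), apart from replicates 1 (12.2 and 7.95) and 3 (4.34 and 5.74). Of the 10 shifted lists, 0 passed with an estimated correlation, 10 to 12 lists passed without 1 array, and 8 of the 10 passed in each of the other alternatives; the mitotic list did not in fry (adjusted p = 0.0806, range over its alternatives 5.08e-05 to 0.549, the last with an estimated correlation) or scaled to the spike-ins (0.0601), nor the ribosomal list scaled to the spike-ins (0.0872, range 2.31e-06 to 0.459, the last with an estimated correlation). Leaving EHMT2 out of the lists gave 12, the added ones being the H3K9 and autophagy lists (adjusted p = 0.0464 each). The autophagy list does not contain EHMT2, so its members were unchanged. It moved from a camera adjusted p of 0.0506 only through the adjustment over the lists. Scaled to the spike-ins, the medians of the 6 lists called higher fell below 0, from -0.00233 for the TGF-beta and YAP targets to -0.16 for the mitotic genes. The direction given by the list tests, of which camera compares a list with the other genes, reversed only for lists that were not called. These were the ATF4 list after quantile normalization (adjusted p = 0.955), cyclic loess (0.937) and in leave-one-out fits (0.741 to 0.892), the cholesterol list at or above the median brightness (0.899) and scaled to the spike-ins (0.95), the mesenchymal list in fry (0.187), scaled to the spike-ins (0.64) and in leave-one-out fits (0.626 to 0.921), the interferon list scaled to the spike-ins (0.95), and the fibroblast list scaled to the spike-ins (0.95) and in leave-one-out fits (0.588 to 0.994); the cause was not tested. Of 94 named genes past the threshold, not counting EHMT2, 21 passed in all alternatives run on them and 43 in all but treat and the stricter threshold, and 0 changed direction; the filter at the median brightness left 73 of them. The 10 splits of 6 arrays into 3 and 3 are too few for a share under 0.05: in 1 split, the real one, the counts were 1778, 577 and 10 lists, against at most 0, 6 and 5 in the others. Signal limits the rest, since 76.1% to 77.2% of probe sets in siNC and 72.8% to 75.1% in siG9a were above the negative controls' 95th percentile.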

Other observations

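The grouping of genes by symbol, and the test of neighbours without pairs of 1 gene family, were chosen after the values had been seen. Genes were grouped by the letters that begin their symbols, and 240 such groups of at least 10 genes were tested with camera. Of these, 22 passed an adjusted p of 0.05, 15 higher and 7 lower, and none did with an estimated correlation (lowest adjusted p 0.633). The median change of all probe sets rose with brightness, and these groups were not compared with random lists matched on it. Mitochondrial ribosomal protein genes lay higher: of 27 MRPS genes 6 rose and none fell (median 0.19, adjusted p = 7.92e-05), led by MRPS9 (0.70) and MRPS7 (0.55), and of 47 MRPL genes 9 rose and none fell (median 0.15, adjusted p = 0.00294), led by MRPL58 (0.72). Of 49 translation initiation factor genes and relatives (EIF), 8 rose and 2 fell (adjusted p = 0.00145), with EIF3F (0.60) highest and EIF4G1 (-0.74) lowest. The SF group, mostly subunits of the splicing factors SF3A and SF3B, had 4 of 10 higher (adjusted p = 0.00231), with SF3B3 (0.88, SE 0.085) and SF3B2 (0.49) in front. Among 10 UTP genes, which act in ribosome assembly, UTP20 (1.01) and UTP23 (0.56) rose (adjusted p = 0.0384). These shifts are relative to other genes: scaling to the poly-A spike-ins lowers each value by 0.294, which puts the medians of the MRPS, MRPL, EIF (0.125) and UTP (0.254) groups below 0, while that of the SF group (0.315) stays above it. The group of symbols beginning with RPL passed as higher too (median 0.166, camera, adjusted p = 0.00286). The group beginning with RPS did not pass (median 0.106, camera, adjusted p = 0.115). It is not made up of ribosomal protein genes alone, since the letters also take in S6 kinase genes such as RPS6KB2 (-0.396), the 1 member that fell.

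On the lower side, 4 of 10 pregnancy-specific glycoprotein genes fell and none rose (median -0.34, adjusted p = 0.00294), with PSG1 (-0.92) and PSG9 (-0.62) lowest; these are near-identical copies, so single members are uncertain, and 1 of the 4, PSG7, was not above the negative controls' 95th percentile on any array. Of 19 semaphorin genes 4 fell and none rose (adjusted p = 0.0384), SEMA5A (-0.74), SEMA4B (-0.51), SEMA3F (-0.48, above the negative controls on 1 of 3 siG9a arrays) and SEMA7A (-0.35).

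Because G9a marks broad stretches of chromatin, one hypothesis was that genes which rise after its knockdown lie next to each other. Of 15886 adjacent, non-overlapping pairs of measured genes in RefSeq order, 34 held 2 risers, against a median of 36 and a 95th percentile of 46 in 10000 random draws matched on brightness (permutation p = 0.65), so these data gave no support for it. For genes that fell, 46 pairs were found against a 95th percentile of 41 (permutation p = 0.0068). Pairs of 1 gene family may account for this: without pairs whose symbols begin with the same letters, such as IFIT2 with IFIT3 or APOBEC3C with APOBEC3D, 34 pairs remained, at or below the 95th percentile of 38 (permutation p = 0.24). Whether the members fall together or share probe signal as similar sequences was not tested.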
